A study of Mus musculus with 2 samples.

How the data were processed

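The series holds 2 libraries of single cells, 1 from the pancreas of a Setd2 WT mouse and 1 from a Setd2 KO mouse, both with mutant Kras and Trp53, so there was 1 mouse per genotype. Per the labels' protocols, tumour leukocytes were isolated with collagenase IV at 2 mg/ml for 30 min with vortexing every 10 min and a 70 µm filter, while the study's design speaks of all cell types. No sort or gate is stated. Libraries were made with the version 3 kit for 3′ ends. Per the submitters' processing notes, CASAVA 1.8 made the reads, and Cell Ranger and Seurat were used with mm10. The values are raw UMI counts in a matrix of genes by barcodes, written as deposited by software version 3.1.0 per the file headers. For the Setd2 WT library barcodes, gene names and the matrix were used. For the Setd2 KO library barcodes and gene names were used, and its expression was not analysed here.

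All other values were computed with Python 3.11.15, scanpy 1.11.5, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, leidenalg 0.10.2 and python-igraph 0.11.9. The matrix had 30905 gene entries, of which 65 shared a symbol with another and were summed, leaving 30840 symbols. Gene IDs matched GENCODE release 21 for 30766 entries, 99.6%, which gave the GRCm38 positions. Barcodes with fewer than 200 genes (406) or more than 20% mitochondrial UMIs (580), 673 in all, were left out, and 4056 passed. Doublets were called with Scrublet at an expected rate of 4%. Its default neighbour search marked 3 cells, and after this was seen an exact search was adopted, which marked 51 cells and left 4005 with 40000106 UMIs. The cell filter, the clustering settings, the gene lists, the markers, the contrasts and the rule for named genes were fixed before the data were examined.

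Counts were scaled to 10000 UMIs per cell and logged, and 2000 variable genes were chosen from genes seen in at least 5 cells, without mitochondrial, ribosomal and list genes. Scaled values were capped at 10. Clustering used 30 principal components, 15 neighbours, Leiden resolution 1 and seed 0, and gave 24 clusters. Clusters were named from 25 marker lists with 226 genes. A marker counted when it was detected in at least 25% of the cluster's cells at a log2 ratio of at least 1, and a name needed at least 3 markers and 50% of those measured. A cluster stayed unnamed when an unrelated class that met this rule had a mean log2 ratio no more than 1 below the best. It also stayed unnamed when its median lay below 2286 UMIs and no marker of the best class was among its 10 leading genes. This depth rule left a cluster of 467 cells with a median of 1553 UMIs unnamed. An endothelial cluster with a median of 1356 UMIs kept its name through 2 markers among its leading genes. These thresholds of the naming rule and the step that separates T cell types were set after the clusters had been seen. T and NK clusters were clustered again and named with 4 lists. Identity genes are the 5 of largest ratio with at least 50 UMIs in the cluster and are not results. The 10 leading genes had also to be detected in at least 25% of the cluster's cells. Clusters are described below by genes of either kind.

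Levels are CPM of UMIs summed over the cells of a class, with exact Poisson 95% intervals, and shares have exact binomial intervals. Both describe counting error alone, since cells are not replicates. The 28 gene lists covered the mutated genes, H3K36 methylation, MAPK output, p53 targets, classical and basal-like cancer, metaplasia, acinar transcription factors, EMT, myofibroblastic, inflammatory and antigen-presenting fibroblasts, lipid handling, matrix remodelling, neutrophil chemoattractants, monocyte and lymphocyte chemokines, myeloid suppression, checkpoint, cytotoxicity, MHC class I and II, interferon, hypoxia and glycolysis, proliferation, stress, unfolded protein response, oxidative phosphorylation and complement. They held 281 genes, of which 265 had at least 20 UMIs in the library, and none of these is a marker. For each list and class of at least 30 cells, the median log2 ratio over all other kept cells, with a pseudocount of 1 UMI, was placed among 10000 random lists matched in 20 bins of expression from 14056 genes. A list or contrast entry counts as higher or lower at 2-fold with separate intervals. Ratios against 0 UMIs are not printed as fold changes, and 3 counts are the floor that 0 allows.

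Named genes followed a rule: Kras, Trp53 and Setd2 in every class, for each list its highest class with members of highest CPM or past the rule of size, and for each contrast up to 30 members in order of ratio. From these 30, genes whose call stayed without the 5 highest cells were preferred. Gsn and Has1 in fibroblast cluster 6 lie beyond the 30, and the genes of the myeloid figure and those of the shares of cells with a UMI were also chosen after their values were seen. Secreted factors needed 50 UMIs. For shares of cells with a UMI each cell was thinned to 1000 UMIs.

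The scripts were tested on simulated data made from this library. With 14056 genes and at least 50 UMIs, the rule of size recovered 15 of 23 genes changed 2-fold, 19 of 19 changed 4-fold, 17 of 17 changed 8-fold and 24 of 24 changed 16-fold, and called 4 of 6100 unchanged genes. With 10900 genes, a list of 10 raised members reached percentile 100, a list of 10 lowered members percentile 0, and 6 of 100 unchanged lists fell outside the central 95%. The intervals of unchanged genes covered the true value in 96.7% of cases, and coverage for changed genes was not measured. Within a group all simulated cells were drawn from the same pooled profile, so they differed only in depth and counting error. Calls that rest on few cells could not arise there, so these rates do not carry over to the contrasts between real cells. Other filters, clustering settings, scalings, pseudocounts, depths, gene minimums, random lists and weights were tried as planned, and 9 further alternatives were added after seeing the data.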

Results

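Single cells were profiled by 3′ droplet RNA sequencing from the pancreas of 2 C57BL/6 mice aged 13 weeks that carried a transgenic model of pancreatic ductal adenocarcinoma. In 1 mouse Kras and Trp53 were mutated and Setd2 was intact (Setd2 WT). In the other, Setd2 was lost as well (Setd2 KO). Kras encodes a small GTPase upstream of MAPK signalling, Trp53 the tumour suppressor p53, and Setd2 the enzyme that trimethylates histone H3 at lysine 36. With 1 mouse per genotype there were no replicates, so no difference below had a replicate check and no test was made. The 95% intervals are exact and cover counting error only. Expression came from the Setd2 WT library, which held 42210625 UMIs (unique molecular identifiers, 1 per captured transcript) over 4729 barcodes, with a median of 5726 UMIs and 1682 genes per barcode. The cell filter and the removal of doublets left 4005 cells with a median of 6859 UMIs. Levels are given as UMIs per 1000000 UMIs (CPM) of summed cells.

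The design sets the Setd2 KO mouse beside the Setd2 WT mouse to ask what loss of Setd2 changes in this tumour. The Setd2 KO library was represented here by its barcodes and gene names, and its expression and cell type shares were not analysed here. It held 5728 barcodes against 4729 in the Setd2 WT library, 999 more, a ratio of 1.21. The gene lists were identical, with 30905 entries each. Differences in tissue mass, loading or barcode calling change such numbers as well as cell content does. In the Setd2 WT library, Setd2 was read at 44.6 CPM (95% interval 42.5 to 46.7). A 3′ tag need not cover the altered part of a gene, so this value checks nothing about the alleles.

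The first question in the Setd2 WT library was which cells it held. Leukocytes made up 1963 of the 4005 cells, 49.0% (95% interval 47.5 to 50.6), and fibroblast-like cells 756, 18.9% (17.7 to 20.1). Monocyte/macrophage-like cells were the largest leukocyte class with 714 cells, 17.8% (16.7 to 19.0), followed by T cell-like cells at 10.6% (9.67 to 11.6), neutrophil-like cells at 6.72% (5.96 to 7.54) and NK cell-like cells at 5.79% (5.09 to 6.56). The dendritic classes were smaller, with type 2 conventional dendritic cell-like cells (cDC2) at 3.17%, type 1 (cDC1) at 1.27% and migratory dendritic cell-like cells at 1.02%. B cell-like cells reached 2.07% and type 2 innate lymphoid cell-like cells (ILC2) 0.524%. Outside the leukocytes, endothelial-like cells made up 10.2% (9.27 to 11.2), acinar-like cells, which bore digestive enzyme transcripts, 4.24% (3.64 to 4.92), and erythroid-like cells 4.22% (3.62 to 4.89). Ductal epithelial-like cells numbered 18, a share of 0.449% (0.267 to 0.709), and this share rose to 1.60% when a cell needed 500 genes and fell to 0 with 4000 variable genes. A further 521 cells, 13.0%, stayed unnamed, 467 of them in a cluster with a median of 1553 UMIs in which 7 of 10 fibroblast markers were raised, and 54 in a cluster led by histone genes and Kif11. When the shallow cluster was counted as fibroblast-like, that class rose to 30.5%. Class names stand for resemblance by fixed markers, and the isolation described for leukocytes can set these shares, although the study's design speaks of all cell types and no sort or gate is stated.

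**Figure D1:**
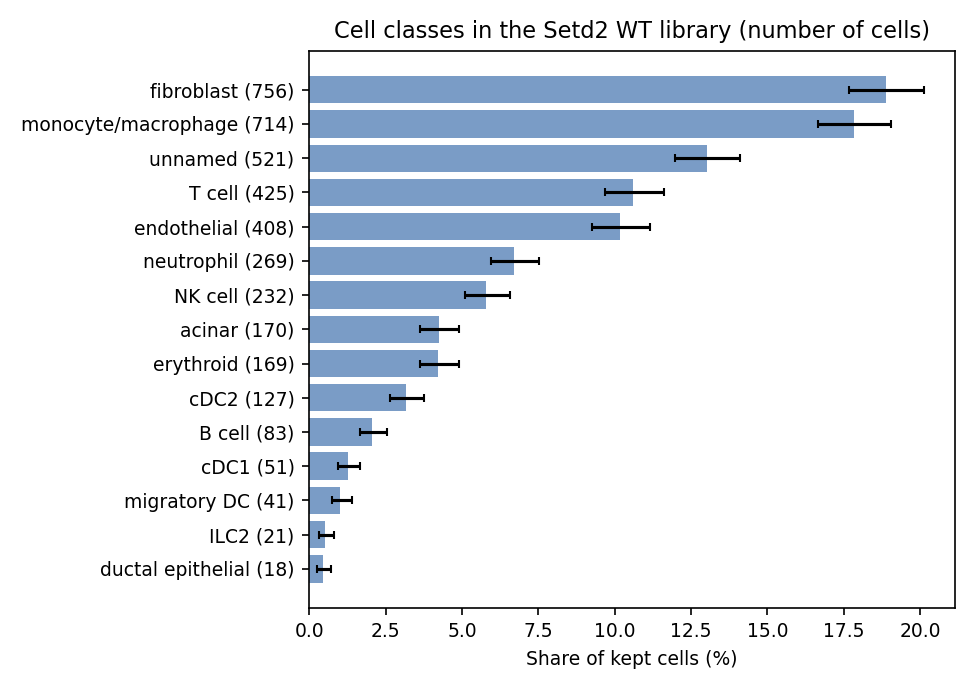
Horizontal bars give the share of the 4005 kept cells in each class of the Setd2 WT library, in percent, with the number of cells beside each name and lines for exact binomial 95% intervals. Fibroblast-like and monocyte/macrophage-like cells had the longest bars, 18.9% and 17.8%, and ductal epithelial-like cells the shortest, 0.449%.

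Re-clustering of the 657 T and NK cells gave NK-like cells at 35.9% (32.2 to 39.7), CD4 T-like cells at 32.1% (28.6 to 35.8) and CD8 T-like cells at 16.3% (13.5 to 19.3). Regulatory T-like cells, identified by Foxp3 and Tnfrsf4, made up 13.1% (10.6 to 15.9), and γδ T-like cells, identified by Trdc and Il17a, 2.59% (1.51 to 4.11). Among the monocyte/macrophage clusters, cluster 2 was identified by Chil3 and Ms4a4c, with 3 monocyte markers among its 10 leading genes, cluster 5 by Lyz1 and Retnla, and cluster 12 by Lyve1, Folr2 and Cbr2. Fibroblast cluster 1 was identified by Ncam1 and Fgf9, cluster 6 by Opcml and Efhd1, and cluster 13 by Lamc3 and Col6a6. These genes describe identity and are not results.

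The genes altered in the model were read in every class. Kras (ENSMUSG00000030265, GRCm38 chromosome 6, 145216699 to 145250239, minus strand) stood at 50.8 CPM over all kept cells (48.6 to 53.1), with 161 CPM in neutrophils (135 to 190), 80.9 in T cells (70.6 to 92.2), 50.8 in fibroblasts (46.6 to 55.4) and 64.0 in ductal cells (35.0 to 107, from 14 UMIs). Trp53 (ENSMUSG00000059552, chromosome 11, 69580359 to 69591873, plus strand) stood at 44.8 CPM (42.8 to 46.9) and was highest among the classes of at least 30 cells in T cells, 93.2 (82.2 to 105), and NK cells, 91.7 (77.8 to 107), against 7.93 in neutrophils (3.19 to 16.3, from 7 UMIs). Setd2 (ENSMUSG00000044791, chromosome 9, 110532597 to 110618633, plus strand) reached 87.5 CPM in NK cells (73.9 to 103) and 75.6 in endothelial cells (66.0 to 86.1), against 35.9 in fibroblasts (32.3 to 39.7). Kras, Trp53 and Setd2 stood at 65.2, 64.1 and 68.3 CPM in cDC2, 61.8, 38.8 and 59.9 in monocyte/macrophages, 50.3, 64.7 and 50.3 in cDC1, 55.5, 45.1 and 63.2 in B cells and 38.2, 19.1 and 59.2 in migratory dendritic cells. All 3 are protein-coding genes. Their low CPM in acinar cells, 15.2, 3.37 and 6.18 for Kras, Trp53 and Setd2, is a share of a total that digestive enzyme transcripts dominate, and in B cells 10 cells with a Jchain UMI held 51.9% of the class's UMIs. The median of the list of all 3 was highest in NK cells, at a log2 ratio of 1.04 over all other cells and the 95th percentile of random lists, but the B cell median rose from 0.16 to 1.15 without those 10 cells.

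**Figure D2:**
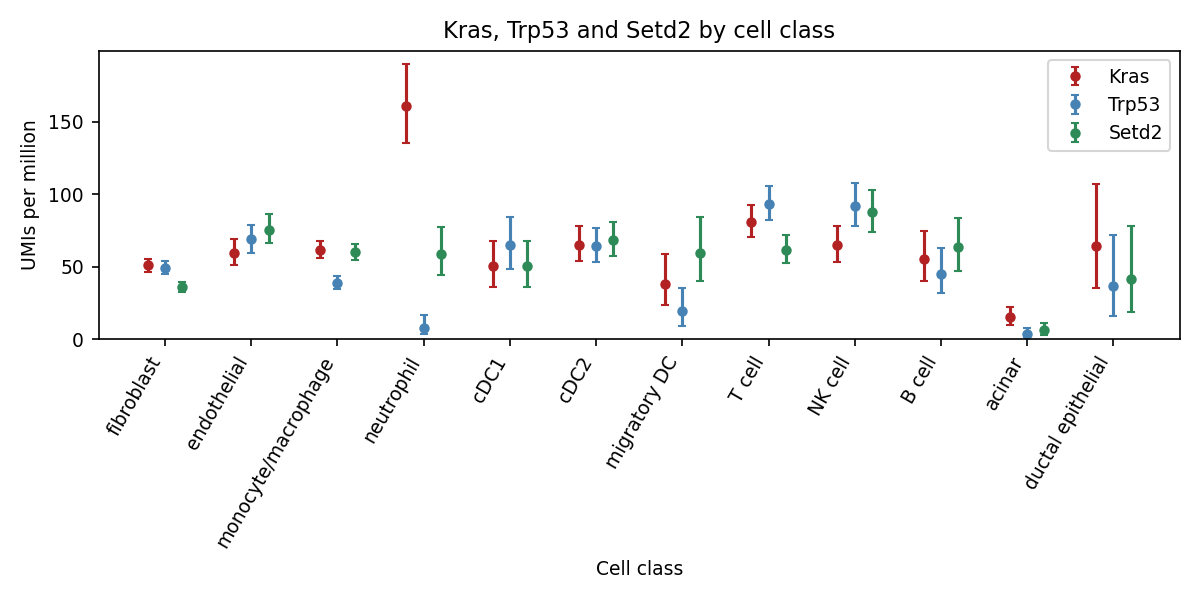
Points give Kras, Trp53 and Setd2 in CPM by cell class of the Setd2 WT library, with exact Poisson 95% intervals. Kras was highest in neutrophils, 161, where Trp53 was 7.93, and the erythroid class, with Kras at 0.901, is left out, as are ILC2-like and unnamed cells.

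Gene lists fixed in advance were then compared between classes, each by the median log2 ratio of its members in a class over all other kept cells, set against 10000 random lists of matched expression. Of 336 pairs of a list and a class, 40 lay at or above the 97.5th percentile with a median above 0. A further 149 lay at or below the 2.5th percentile. Lists of independently drawn genes would put 8.4 pairs in each of these tails. The fixed lists hold genes of shared function and some overlap, so an excess over 8.4 is no evidence by itself. Several also describe programmes of the named classes, such as matrix genes in fibroblasts and cytotoxicity in NK cells, so their high rank was partly given in advance. Of the 40, 24 kept their place in all 12 other settings, and the acinar transcription factors in acinar cells in the 10 that gave a value. Fibroblasts carried the matrix programmes. The myofibroblastic list stood at a median of 5.21 with 10 of 11 members at least 2-fold higher, among them Postn, a matricellular protein (983 CPM, 44.3-fold), Cthrc1, a secreted protein of matrix-producing fibroblasts (263 CPM, 47.9-fold), and the collagen genes Col8a1 and Col12a1 (221 and 204 CPM). The matrix remodelling list stood at 5.0 with 10 of 10 higher, including the proteoglycan gene Bgn (1995 CPM, 32.3-fold), the protease inhibitor Timp1 (1424 CPM, 20.6-fold), the gelatinase Mmp2 (672 CPM, 46.1-fold) and the collagen cross-linker Lox (525 CPM, 45.1-fold). The inflammatory fibroblast list stood at 3.37 with 9 of 12 higher, led by C3 (4106 CPM, 23.3-fold), the actin-severing protein Gsn (2802 CPM, 13.2-fold) and Clec3b (1382 CPM, 28.9-fold). The complement list stood at 4.07 with 8 of 11 higher, including the C1 inhibitor gene Serping1 (2496 CPM, 25.9-fold), while 3 members were lower, Cfp and the receptors C5ar1 and C3ar1. The EMT list stood at 2.04 with 7 of 10 higher, led by Sparc (8821 CPM, 20.2-fold) and Vim (2991 CPM, 3.42-fold), both also ordinary products of mesenchymal cells, and Tgfbi was lower.

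Myeloid classes carried the chemokine, suppression and interferon lists. Neutrophil chemoattractants and growth factors stood highest in neutrophils, at 2.30 with 7 of 10 higher and 2 lower, led by the cytokine Il1b (22581 CPM, 22.6-fold), the CXCR2 ligands Cxcl2 (20365 CPM, 29.1-fold) and Cxcl3 (305 CPM, 45.1-fold), and at 1.76 in monocyte/macrophages, which fell to 0.45 with per-cell CPM and 0.65 with thinning, both below the 97.5th percentile. Monocyte and lymphocyte chemokines stood at 1.65 in monocyte/macrophages with 6 of 11 higher and 2 lower, among them Ccl2 (581 CPM, 5.11-fold), Ccl3 (519 CPM, 6.49-fold) and the interferon-induced Cxcl10 (277 CPM, 8.03-fold). Myeloid suppression genes stood at 1.95 in the same class with 7 of 10 higher, including Wfdc17 (1460 CPM), the prostaglandin synthase Ptgs2 (892 CPM) and the interleukin 1 antagonist Il1rn (246 CPM, 8.17-fold), and at 1.41 in neutrophils. The interferon list stood at 1.44 in monocyte/macrophages with 6 of 11 higher, among them the transcription factor Irf7 (126 CPM, 5.27-fold), and at 0.86 in neutrophils. MHC class II genes, which present peptides to CD4 T cells, stood at 2.88 in cDC2 with 10 of 10 higher, led by Cd74 (20892 CPM, 8.05-fold) and H2-Ab1 (9008 CPM, 7.78-fold), then at 2.48 in cDC1, 1.96 in monocyte/macrophages and 1.79 in migratory dendritic cells. The antigen-presenting fibroblast list gave the same cDC2 median of 2.88, since 4 of its 6 members are those MHC class II genes, while its other members Slpi and Saa3 were lower there. MHC class I presentation stood at 1.55 in migratory dendritic cells with 9 of 10 higher, led by B2m (3346 CPM, 2.59-fold) and the immunoproteasome subunit Psmb8 (1243 CPM, 5.74-fold), and at 1.29 in T cells and 1.18 in NK cells, the latter 0.65 and the 97.3rd percentile against the mean of the other classes.

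Lymphocytes and acinar cells carried their own programmes. Cytotoxicity genes stood at 4.95 in NK cells with 8 of 9 higher, among them the granzyme Gzma (3051 CPM, 142-fold), the pore-forming Prf1 (367 CPM, 126-fold) and Nkg7 (2256 CPM, 30.9-fold), and at 2.19 in T cells. The checkpoint list stood at 2.67 in T cells with 7 of 10 higher, led by Ctla4 (341 CPM, 53.6-fold), Pdcd1 (112 CPM, 46.4-fold) and the transcription factor Tox (97.6 CPM, 11.8-fold), all of them linked to restrained T cell responses, and Entpd1 was lower. Acinar transcription factors stood at 5.99 in acinar cells with 4 of 4 higher, including Rbpjl (43.8 CPM, 106-fold) and Ptf1a (24.2 CPM, 118-fold). In acinar cells the metaplasia list stood at 0.86, above random lists, which ran from -3.26 to -1.43, with the regenerating-family genes Reg1 (33659 CPM, 303-fold) and Reg3b (7242 CPM, 225-fold) higher and the osteopontin gene Spp1 lower. Immediate early stress genes, which rise during tissue digestion, stood at 0.92 in endothelial cells with 6 of 12 higher, including Jun (3884 CPM, 5.35-fold) and Egr1 (3063 CPM, 3.85-fold), at the 95.1st percentile of unmatched lists against the 99.9th of matched ones.

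Unfolded protein response genes stood at 1.05 in fibroblasts with 5 of 10 higher, and fell to the 96.9th percentile with unmatched random lists and to the 95.3rd against the mean of the other classes. In B cells they stood at 1.16, where the median fell to -0.33 without the 10 cells with a Jchain UMI, to 0.03 with per-cell CPM and to 0.42 with thinning. Proliferation stood at 1.05 in cDC1 with 6 of 12 higher, but a single cell held 37.8% of the Stmn1 UMIs and 52.8% of those of Top2a, and thinned cells placed the list at the 34.6th percentile. The 54 cells of the unnamed cluster led by histone genes belonged to no class here. Of these, 29 correlated best with monocyte/macrophages, 9 with NK cells, 8 with T cells, 7 with cDC2 and 1 with cDC1. The ranking of classes by proliferation therefore leaves them out unequally. The H3K36 methylation list, which holds Setd2, stood highest in endothelial cells, at 0.85 and the 93.3rd percentile, with the methyltransferase Ash1l at 168 CPM (2.59-fold), and at 0.82 and the 98.2nd percentile in NK cells, where it reached the 88.8th when thinned, the 96.3rd against the mean of the other classes and the 97.3rd with unmatched lists. Oxidative phosphorylation stood at 0.67 in both monocyte/macrophages and cDC2, at the 94.6th and 98.9th percentiles, with 0 of 11 members past 2-fold, and thinning lowered the cDC2 value to the 93.7th. The hypoxia and glycolysis list stood at 0.64 in monocyte/macrophages, the 97th percentile, with the glycolytic enzymes Eno1 (345 CPM, 3.47-fold) and Pgk1 (252 CPM, 2.99-fold) higher, and at 0.51 in neutrophils, the 98.5th percentile, which fell to 96.1 when thinned, 97.1 with a pseudocount of 5 and 97.49 with unmatched lists. Lipid handling stood at 0.51 in monocyte/macrophages, the 89.6th percentile, with the lipoprotein gene Apoe at 4046 CPM (20.3-fold) and the adipocyte-type binding protein gene Fabp4 lower. MAPK output reached no more than 0.09, in endothelial cells, although Spry1 (330 CPM, 27-fold) and Dusp6 (169 CPM, 11.4-fold), both feedback inhibitors of that pathway, were higher there. The p53 target list reached 0.16 in monocyte/macrophages, where Cdkn1a, the cell cycle inhibitor, stood at 548 CPM (2.47-fold). The classical and basal-like pancreatic cancer lists had no class with a median above 0, with highest values of -0.27 in neutrophils, the 41.9th percentile, and -0.16 in T cells, the 43.9th. Without the 10 cells with a Jchain UMI, however, the B cell medians were 0.105 and 0.396. These lay at the 5.29th and 37.9th percentiles of random lists. In acinar cells, where enzyme transcripts dominate the total, the classical list stood at -0.62, above random lists, which ran from -2.62 to -0.81, with Tff2 (4701 CPM, 259-fold) and Agr2 (11.2 CPM, 75.2-fold) higher and 4 of 8 members lower. The 18 ductal cells were too few to enter this comparison.

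**Figure D3:**
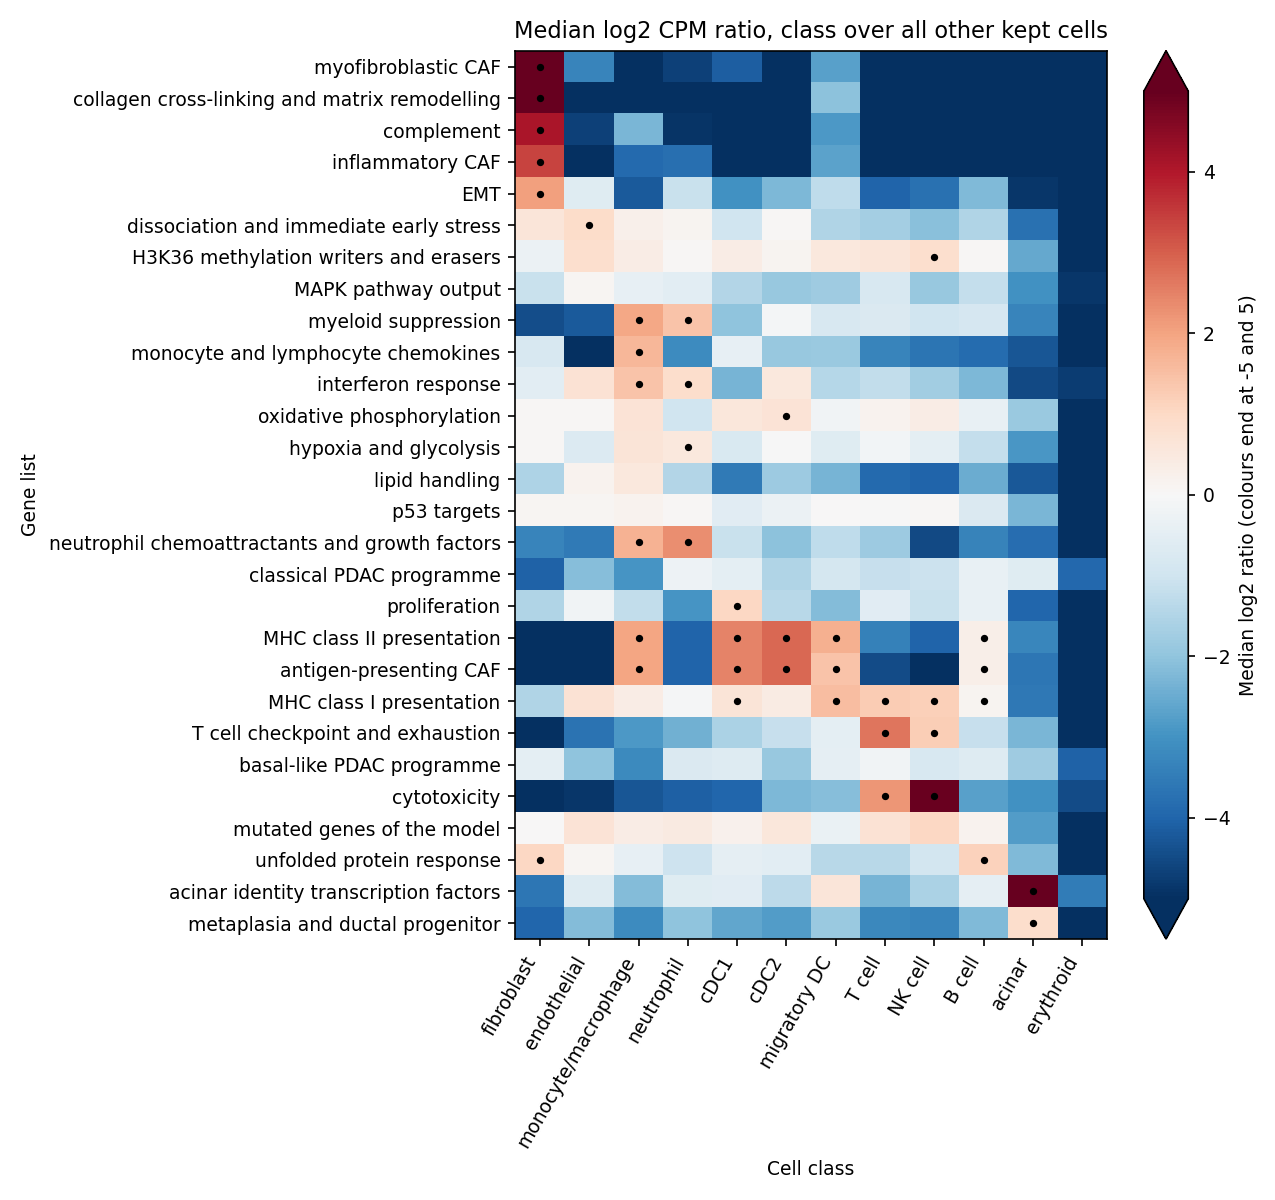
Colours give the median log2 ratio of each of 28 gene lists (vertical axis) in each of 12 classes (horizontal axis) over all other kept cells of the Setd2 WT library, and dots mark the 40 pairs at or above the 97.5th percentile of random lists with a median above 0. The matrix lists peak in fibroblasts, at 5.21 and 5.0, and cytotoxicity in NK cells, at 4.95.

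The epithelial comparison set ductal cells against acinar cells, the compartments between which the tumour model's metaplasia runs. Ductal cells had higher levels of the ductal progenitor genes Spp1 (26509 CPM against 7.31, log2 11.72, 95% interval 11.05 to 12.73), Sox9, a ductal transcription factor (1019 against 3.37, log2 8.02), and Hnf1b (105 against 1.12 from 2 UMIs, log2 6.02, 4.53 to 9.68), and of Apoe (6466 against 8.99). Immediate early genes were higher in 11 of 12 cases at a median log2 ratio of 4.88, including Egr1 (4067 against 50.6), Atf3 (1202 against 16.3), Jun (4423 against 93.3) and Fos (3806 against 105). Oxidative phosphorylation genes were higher in 11 of 11 cases, MHC class I genes in 8 of 10 and unfolded protein response genes in 7 of 10, but their medians of 2.48, 2.39 and 2.21 lay below the 2.55 of all members, so these lists did not stand apart from the general shift. Vegfa, the endothelial growth factor, stood at 256 against 5.62 CPM. Ier2 (1970 against 37.1), Fosb (1887 against 57.3) and Zfp36, an mRNA decay factor (1645 against 61.8), belong to the same early response. Gata6, a transcription factor of the classical tumour type, stood at 169 against 0.562 from 1 UMI (log2 7.27, 5.67 to 13.57). Acinar cells held more Reg3b (7242 CPM against 101 in ductal cells, log2 ratio -6.11), Reg1 (33659 against 512, -6.03), Reg3g (835 against 13.7 from 3 UMIs, -5.51, interval -8.21 to -4.38) and the trefoil factor Tff2 (4701 against 73.1, -5.92). Over all 265 members 105 were at least 2-fold higher in the 18 ductal cells and 17 lower, with a median log2 ratio of 2.55, and 54 and 4 stayed so without the 5 cells with most UMIs of the gene on each side. With totals freed of the most abundant transcripts the counts were 67 and 26, and with cells thinned to 1000 UMIs 34 and 4. The high ductal values of Tff1 and Ctse came from 1 cell, and the acinar enzyme transcript Ctrb1 stood at 2477 CPM in ductal cells against 168677 in acinar cells. Other enzyme transcripts were read there as well, such as Pnlip (462 against 34151) and Clps (2554 against 48010). The low ductal levels of Reg3b, Reg1, Reg3g and Tff2 therefore cannot be told from acinar RNA in ductal droplets.

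Within fibroblasts, cluster 1 (392 cells) was compared with the other 364. It had more of 5 of 11 myofibroblastic members and less of none, among them Acta2, smooth muscle actin (56.1 against 4.04 CPM, log2 3.71, 3.08 to 4.62), Tnc (72.7 against 6.56, log2 3.42) and Igfbp3 (154 against 44.1, log2 1.79). Proliferation genes were higher in 9 of 12 cases, among them Mki67 (15.4 against 1.01 from 4 UMIs, log2 3.62), Birc5 (13.9 against 1.51) and Stmn1 (44.0 against 11.9). The mitotic kinase gene Cdk1 stood at 14.7 against 0.505 from 2 UMIs (log2 4.30, 2.97 to 7.93) and the topoisomerase gene Top2a at 19.6 against 0.757 from 3 UMIs (4.29, 3.11 to 6.99). The acute phase gene Saa3 (63.6 against 1.26), the chaperone gene Clu (63.1 against 12.6) and the chemokines Cxcl9 (40.4 against 12.6) and Cxcl16 (26.9 against 8.32) were also higher. Lower members included the lipid transporter Abca8a (46.1 against 236, log2 -2.35) and Gsn (1317 against 5195, -1.98). The ectonucleotidase Entpd1 (1.88 against 9.84, -2.31) and the laminin chain Lamc2 (4.54 against 14.1, -1.61) were lower as well. In all 30 members were higher and 18 lower, of which 23 and 9 stayed without the 5 highest cells. A count on thinned cells gave 12 and 11, with 10 and 6 of the calls kept. Of its cells 49 had UMIs of at least 2 mesothelial markers, against 2 in cluster 6 and 1 in cluster 13, and without such cells 26 members were higher and 13 lower, 25 and 11 of them among the 30 and 18.

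Fibroblast cluster 6 (248 cells) had less of 4 of 11 myofibroblastic and 4 of 10 matrix remodelling members than the other 508 cells, and more of none. Of those 508 cells 392 belong to cluster 1, so the 2 contrasts share cells and opposite signs are partly built in. Acta2 stood at 1.51 against 52.5 CPM (log2 -4.86, -6.75 to -3.88), Igfbp3 at 15.7 against 157 (-3.29), Tagln, a further smooth muscle gene, at 23.8 against 196 (-3.02) and Apoe at 57.4 against 340 (-2.56). Tnc stood at 0.604 from 2 UMIs against 69.4 (-6.26, -9.89 to -4.98). Clu (14.2 against 57.7, -2.00), Birc5 (1.81 against 12.7, -2.60) and Cxcl16 (6.94 against 25.9, -1.84) were lower, and Entpd1 (10.6 against 2.27, 2.17) and Cd274, a checkpoint ligand (6.04 against 1.56, 1.89), higher. Proliferation members were lower in 9 of 12 cases, including Mki67 (1.21 against 13.9), and the MAPK feedback gene Spry1 stood at 6.34 against 24.7. Gsn (4544 against 1982, log2 1.20) and the hyaluronan synthase Has1 (292 against 137, log2 1.09) were higher. In all 19 members were higher and 37 lower, but the count of higher ones was 12 with the mean of per-cell CPM, and 8 and 28 calls stayed without the 5 highest cells. Thinned cells gave 7 and 17, with 5 and 12 of the calls kept, and without the cells with mesothelial markers 14 and 29 calls stayed.

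Fibroblast cluster 13 (116 cells) had more of 6 of 14 lipid members than the other 640 cells, and less of 5 of 11 myofibroblastic, 6 of 12 inflammatory and 5 of 11 chemokine members, with 1, 2 and 0 higher. Abca8a stood at 969 against 61.7 CPM (log2 3.97, 3.81 to 4.14), the lipoprotein lipase gene Lpl at 1228 against 205 (2.58) and Apoe at 940 against 203 (2.21), and 3 of the 6 lipid calls stayed without the 5 highest cells. MAPK output members were higher in 6 of 11 cases, 3 of which stayed without the 5 highest cells, among them the feedback genes Spry1 (134 against 11.1, log2 3.59), Spry4 (20 against 1.65) and Dusp6 (27.6 against 4.64), as was the collagen-binding Fmod (49.1 against 5.77). Sox9 stood at 23.0 against 4.43 (2.44). Lower members included Col8a1 (12.3 against 235, log2 -4.09), Col12a1 (20 against 217), Cthrc1 (29.2 against 279), Postn (180 against 1036, -2.52) and Pi16 (124 against 1012, -3.01). The chemokines Ccl7 (33.8 against 311) and Ccl2 (41.5 against 297) were lower, as was Ptgs2 (39.9 against 402). Ly6c1, a surface protein of inflammatory fibroblasts (286 against 1214, -2.08), and Gata6 (9.21 against 50.2, -2.23) were lower too. In all 29 members were higher and 43 lower. Without the 5 highest cells 12 and 32 of these calls stayed, while a pseudocount of 5 gave 29 and 26. Thinned cells gave 11 and 20, with 10 and 20 of the calls kept.

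Among monocyte/macrophages, cluster 2 (331 cells) carried the interferon response, with 11 of 11 members higher than in the other 383 cells at a median log2 ratio of 2.10. Examples were Irf7 (238 against 21.9 CPM, log2 3.43, 3.12 to 3.79), Ifit3 (59.6 against 6.51, 3.15) and Ifit2 (57.1 against 1.56, 4.98). Il1b stood at 6991 against 925 (2.92), the chemokine Ccl3 at 895 against 168 (2.42), C3 at 148 against 26.8, the secreted inhibitor Slpi at 109 against 8.07 and the hypoxia-induced Ndrg1 at 79.7 against 12.0. The cytokine Lif stood at 32.6 against 3.39 (3.17). Proliferation members were lower in 10 of 12 cases, including Birc5 (1.11 from 4 UMIs against 22.7) and Stmn1 (5.29 against 62.2). Mcm5 (3.34 against 25, -2.80), the p53 target Phlda3 (1.67 against 13.3, -2.80) and Cd24a, a progenitor surface protein (17.3 against 252, -3.85), were lower too. Lpl (76.6 against 1009, log2 -3.71), the fatty acid receptor Cd36 (13.1 against 83.1), the phospholipid transfer gene Pltp (92.5 against 519), C4b (26.8 against 201) and Ccl8 (3.90 against 222) were lower. In all 37 were higher and 33 lower, with 35 and 26 of these calls kept without the 5 highest cells. Thinned cells gave 30 and 13, with 24 and 11 of the calls kept. The unnamed cluster led by histone genes, where 29 of 54 cells correlated best with monocyte/macrophages, lay outside the contrasts of clusters 2, 5 and 12. Which of these clusters its cells resemble was not tested, which limits their proliferation calls.

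Cluster 5 (263 cells) had lower interferon genes and higher proliferation genes than the other 451 cells. Of these 331 belong to cluster 2, so opposite signs to that contrast are partly built in, but cluster 12, with Irf7 at 57.4 CPM (41.8 to 76.8) and Stmn1 at 33.1 (21.7 to 48.6), lay between the other 2. All 11 interferon members were lower, at a median of -2.14, including Irf7 (12.8 against 206 CPM, log2 -3.98), Ifit3 (1.31 from 4 UMIs against 53.7) and Oasl2 (16 against 121). Proliferation was higher in 10 of 12 cases at a median of 2.87, including Stmn1 (69.7 against 10.3), Mcm5, a replication licensing gene (30.4 against 3.43), Ccnb2 (23.2 against 2.29) and Birc5 (25.5 against 2.97). Lpl stood at 1236 against 85.3 (log2 3.85, 3.70 to 4.01) and Cd24a at 313 against 17.4. The chemokine Cxcl9 (13.1 against 1.14, 3.29) and Phlda3 (16.4 against 1.60, 3.19) were higher. Apoe (523 against 6508, -3.64), Spp1 (22.6 against 191), Ccl3 (123 against 796), Saa3 (9.16 against 157) and the complement genes C3 (20.9 against 131) and Cfb (6.54 against 41.9) were lower. Ccl8 (1.64 against 197, -6.65), Slpi (5.24 against 92.9, -4.06), Ndrg1 (7.85 against 70.4, -3.11) and Havcr2, a checkpoint receptor (2.94 against 22.2, -2.78), were lower as well. In all 25 members were higher and 49 lower, of which 20 and 43 stayed without the 5 highest cells. With the mean of per-cell CPM 44 of the 49 lower calls stayed and 2 turned to higher. Thinned cells gave 12 and 38, with 9 and 31 of the calls kept.

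Cluster 12 (120 cells) had the highest Ccl8, a monocyte chemoattractant, at 1080 CPM against 2.86 in the other 594 cells (log2 8.49, 7.91 to 9.30). C4b (602 against 59.5, 3.34), Cfh, a complement regulator (463 against 70.9, 2.71), Ccl7 (578 against 163, 1.83), Apoe (12607 against 3035, 2.05) and the cholesterol exporter Abca1 (133 against 39.6, 1.75) were also higher. The stress transcription factor Ddit3 stood at 49.7 against 15.4 (1.72). Il1b (538 against 4246, -2.98), Cxcl10 (33.1 against 306, -3.15), Vegfa (10.2 against 70.6), Lpl (125 against 610), Ptgs2 (261 against 966) and the interferon-stimulated Isg15 (56.1 against 197, -1.78) were lower, as were 5 of 13 hypoxia members, among them the glucose transporter Slc2a1 (5.10 from 4 UMIs against 24.1). Cd24a (17.8 against 153, -3.00) and Ifit2 (6.37 against 31, -2.03) were lower too. In all 31 members were higher and 25 lower, but neither count was stable, and more of the higher calls were lost. Recounted without the 5 highest cells, 14 were higher and 49 lower. Of the calls 14 and 24 were kept, and 1 higher member moved to the other side. Without the highest cell 19 were higher and 33 lower, with 19 and 24 kept. Thinned cells gave 15 and 17, with 15 and 11 kept.

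**Figure D4:**
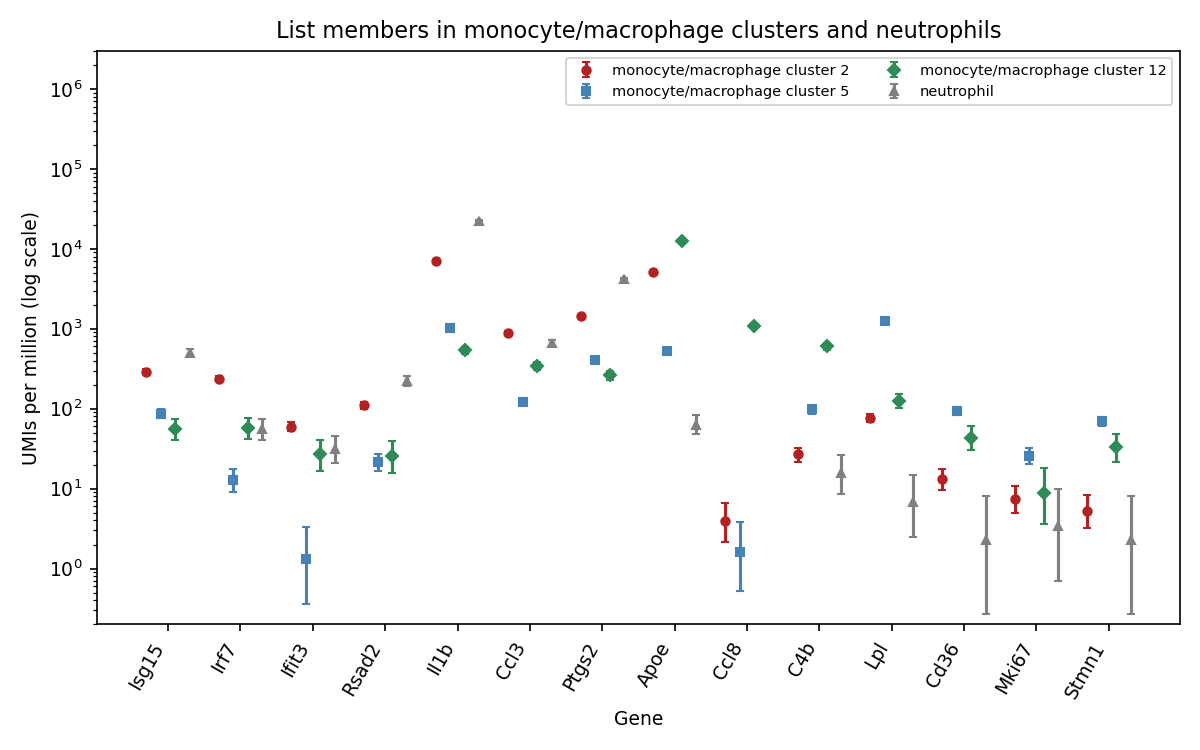
Points give list members in CPM on a log scale in the 3 monocyte/macrophage clusters and in neutrophils of the Setd2 WT library, with exact Poisson 95% intervals, for genes picked after their values were seen. Irf7 stood at 238 in cluster 2 and 12.8 in cluster 5, Lpl at 76.6 and 1236, Ccl8 at 1080 in cluster 12, and Ccl8 has no neutrophil point because it had 0 UMIs there.

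Monocyte/macrophages (714 cells) and neutrophils (269 cells) differed in antigen presentation, chemokines and energy genes. MHC class II members were higher in monocyte/macrophages in 8 of 10 cases, including H2-Aa (4013 against 51.0 CPM, log2 6.27, 5.88 to 6.75), H2-Eb1 (2994 against 53.2), H2-Ab1 (3880 against 87.2), H2-DMa (612 against 10.2) and Cd74 (8513 against 242). The lipid genes Lpl (559 against 6.79), Apoe (4046 against 63.4) and Pltp (313 against 4.53 from 4 UMIs), the chemokine Ccl2 (581 against 11.3, 5.54), the cytokine Il6 (292 against 9.06) and the complement receptor C3ar1 (183 against 5.66) were higher too, as were 9 of 11 oxidative phosphorylation members. The arginine-degrading enzyme Arg1 stood at 109 CPM against 2.26 from 2 UMIs, a log2 ratio of 5.0 (3.73 to 8.63). H2-DMb1 (536 against 7.93) and the chaperones of the endoplasmic reticulum Pdia4 (93.2 against 5.66) and Sdf2l1 (112 against 4.53 from 4 UMIs) were higher. Neutrophils held more of 6 of 10 chemoattractants and growth factors, among them Csf1 (137 against 3.37 CPM in monocyte/macrophages, log2 ratio -5.30), and more Slpi (1891 against 56.8, -5.05), Dgat1, a triglyceride synthase (463 against 23.4, -4.30), Snai1 (83.8 against 1.75), the oxygen sensor Egln3 (61.1 against 2.15, -4.77) and the AP-1 gene Fosl1 (26 against 1.62, -3.96). In all 80 members were higher in monocyte/macrophages and 47 lower, of which 77 and 40 stayed without the 5 highest cells.

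T cells (425) were set against NK cells (232). Cytotoxicity was lower in T cells for 8 of 9 members, including Gzma (71.8 against 3051 CPM, log2 -5.40, -5.62 to -5.20), Prf1 (16 against 367, -4.49), Gzmb (39.3 against 372, -3.23) and the cathepsin Ctsw (129 against 504, -1.96), and Gzmk was the exception (98.0 against 1.20 from 2 UMIs, log2 5.77, 4.49 to 9.41). T cells held more Ctla4 (341 against 8.99, 5.15) and Pdcd1 (112 against 1.20 from 2 UMIs, 5.96, 4.68 to 9.60), and less Cd160 (28.4 against 153, -2.42). The chemokines Ccl3 (26.6 against 520, -4.27) and Ccl4 (312 against 1927, -2.62) and the MAPK inhibitor Spry2 (27.0 against 433, -3.99) were lower in T cells, and Cxcl10 (66.3 against 5.99) and the cytokine Tnf (37.1 against 8.99) higher. Cxcl2 (122 against 7.19, 3.97) was higher and Vegfa (2.55 against 37.8, -3.72) lower. In all 30 members were higher and 21 lower, of which 24 and 18 stayed without the 5 highest cells. A count on thinned cells gave 14 and 15, with 12 and 14 of the calls kept.

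Among T cells, CD8 T-like cells (107) were set against regulatory T-like cells (86). The CD8 T-like cells joined a sub-cluster of 65 cells, with Dapl1, Lef1 and Tcf7 among its leading genes, and another of 42 cells, with Gzmb, Ctsw and Ccl5 among its own. Values for CD8 T-like cells are sums over both and need not describe either. Cytotoxicity was higher in CD8 T-like cells for 8 of 9 members, including Gzma (249 CPM against 1.66 from 1 UMI, log2 6.24, 4.74 to 12.54) and Nkg7 (965 against 84.7, 3.49), and so were Ccl4 (276 against 14.9, 4.06) and Ccl5 (5746 against 730, 2.97), chemokines of activated lymphocytes. Regulatory T-like cells held more of 5 of 10 checkpoint members, among them Ctla4 (968 against 48.5 in CD8 T-like cells, -4.28), the costimulatory receptor Tnfrsf9 (266 against 6.74, -5.05) and Pdcd1 (212 against 24.3, -3.06), and more Cd74 (549 against 27.0, -4.28) and H2-Eb1 (103 against 10.8, -3.11). Stress genes were lower in CD8 T-like cells in 7 of 12 cases and higher in 3, and MHC class II genes lower in 5 of 10, of which 6, 1 and 3 calls stayed without the 5 highest cells. The death ligand Fasl stood at 62.0 in CD8 T-like cells against 4.98 from 3 UMIs (3.25, 2.00 to 5.97). Dusp4, a MAPK phosphatase, stood at 136 against 1.35 from 1 UMI (-5.68, -11.98 to -4.14), and Cxcl2 at 355 against 2.70 from 2 UMIs (-6.46, -10.10 to -5.17). Tff1, a mucosal trefoil factor, had 71 UMIs in regulatory T-like cells and 0 in CD8 T-like cells, where 3 counts would set the floor. In all 17 members were higher and 45 lower, of which 13 and 29 stayed without the 5 highest cells. A count on thinned cells gave 7 and 19, with 7 and 18 of the calls kept.

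For 30 secreted or suppression factors with at least 50 UMIs, the class holding most UMIs was recorded, and for 20 of them a single class held over 50%. Monocyte/macrophages were the main source of 18, among them Ccl12 (96.3% of UMIs, 93.4 to 98.2), Arg1 (87.2%, 84.8 to 89.2), the anti-inflammatory cytokine Il10 (77.7%, 70.4 to 84.0), Cxcl10 (64.7%) and Ccl2 (53.8%, with 36.2% in fibroblasts). Fibroblasts were the main source of 5, among them Cxcl9 (79.6%, 75.2 to 83.5), the macrophage growth factor Csf1 (79.0%, 77.1 to 80.9) and Cxcl1 (73.9%, 73.0 to 74.9). The 21 ILC2-like cells held 76.4% of Csf2, the granulocyte-macrophage growth factor (67.9 to 83.6; 599 CPM). A share depends on how many cells of each class were captured: neutrophils held 33.7% of Il1b and 39.6% of Cxcl2 at 22581 and 20365 CPM, while monocyte/macrophages held 48.5% and 48.9% at 3855 and 2988 CPM. NK and T cells held 42.8% and 38.8% of Ccl5, and migratory dendritic cells 34.5% of Cxcl16 and 21.1% of the checkpoint ligand Cd274 at 804 and 300 CPM. With every class weighted to the same number of cells, 13 of the 30 had over 50% in a single class and 17 kept their source. Monocyte/macrophages then led 9 instead of 18, and Arg1 was highest in ILC2-like cells (63.0%; 306 CPM against 109 in monocyte/macrophages).

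**Figure D5:**
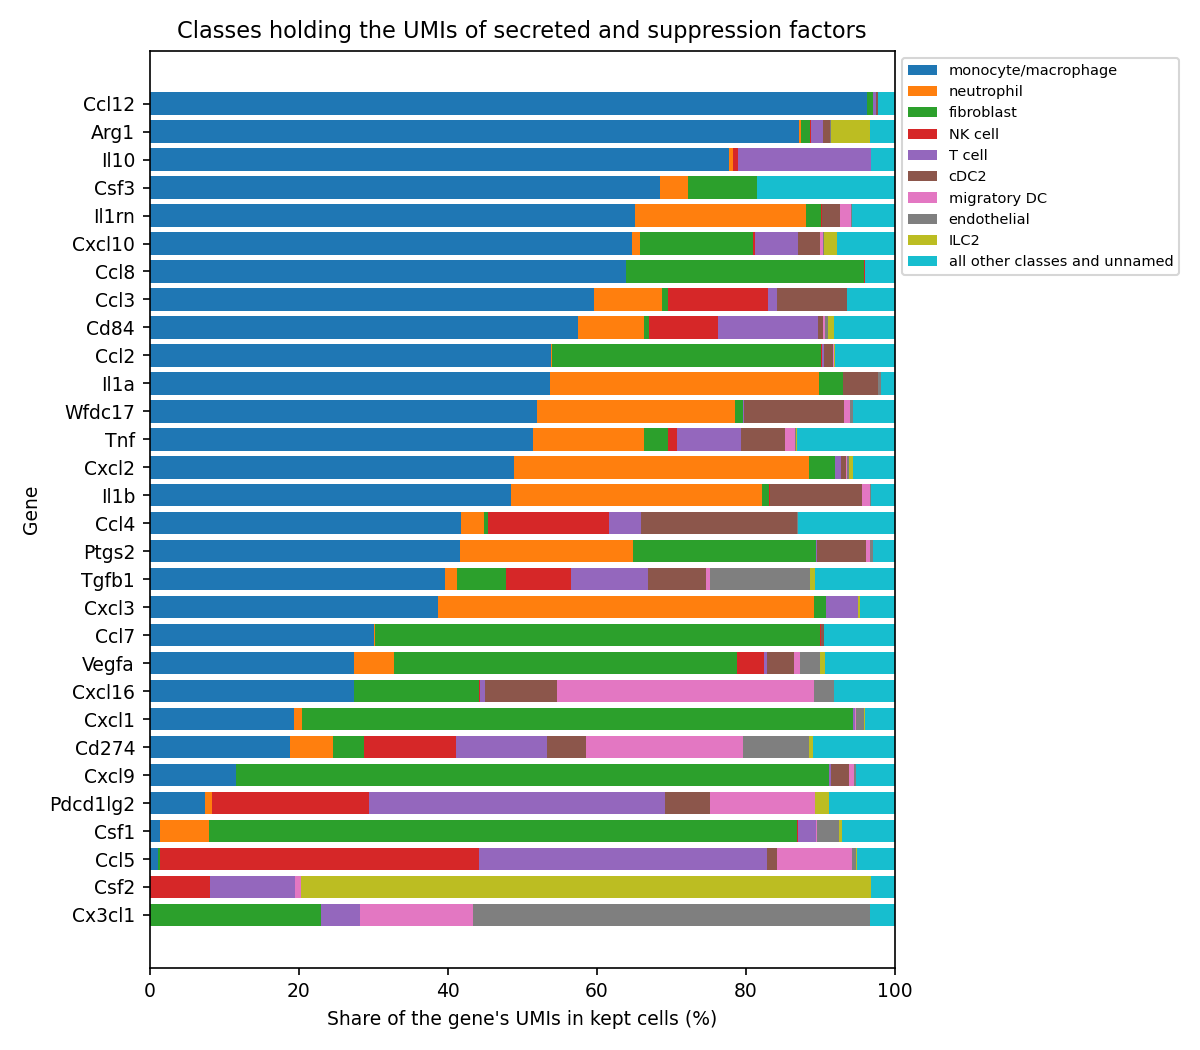
Stacked bars give, for each of 30 factors of the Setd2 WT library, the share of its UMIs in kept cells that each class held, in percent, ordered by the monocyte/macrophage share. Ccl12 tops the order with 96.3% in monocyte/macrophages, and Csf1 and Cxcl9 lie mostly in fibroblasts, with 79.0% and 79.6%.

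Shares of cells with a UMI were compared after thinning each cell to 1000 UMIs, with shallower cells left out. Gzmb was seen in 20.9% of NK cells (15.8 to 26.7, 2 cells left out) and 1.90% of T cells (0.826 to 3.72, 5 left out), against 0 of 753 fibroblasts, a class that should lack it, which allows up to 0.489% (3 left out). Without thinning the shares were 34.9%, 5.88% and 0%, at median depths of 7014, 5859 and 10298 UMIs. Il1b was seen in 98.4% of neutrophils (96.0 to 99.6) and 55.7% of monocyte/macrophages (51.9 to 59.5), and in 2.26% of fibroblasts (1.32 to 3.59), the class set beside them, with 13, 32 and 3 cells left out. Unthinned, these were 99.6%, 68.3% and 11.5% at median depths of 3123, 10410 and 10298 UMIs. Ctla4 was seen in 23.3% of T cells (19.4 to 27.7) and 0.266% of fibroblasts (0.0322 to 0.956), or 45.6% and 0.529% unthinned.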

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

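The tests of the mitochondrial filter and of the isolation below were chosen after the results were seen, and the other 5 were written before their values were known. Signals in data that the comparisons did not use were flagged because they lay above what a count of 0 allows, which shows that they were present and not that they were unusual. Of the barcodes, 10 were present in both libraries, and 9 of them passed the Setd2 WT filter. The 673 barcodes left out by the cell filter held 4.18% of all UMIs with a median of 1101, and 2.27% of their UMIs came from acinar enzyme genes, 47.5% from haemoglobin genes and 24.4% from mitochondrial genes. No biological explanation was tested for any pattern below, since expression was at hand for 1 genotype.

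Few ductal epithelial-like cells were found, 18 of 4005. Loss to the mitochondrial filter was not borne out as the main cause, since the share without a limit was 0.556%, inside its interval of 0.267 to 0.709%, but the number rose from 13 at a limit of 10% to 18 at 20% and 24 without one, so loss of some such cells stays open. An earlier test of both filters asked for at least 3 ductal markers and found 3 of 673 excluded barcodes (0.446%) against 89 of 4005 kept (2.22%), but at 500 UMIs each these fell to 1 (0.149%, 0.00376 to 0.825) and 12 (0.300%, 0.155 to 0.523) and decided nothing, so the filter on gene number stays open. Placement in other clusters could not be told, since 18 cells outside the cluster had at least 5 ductal markers, 17 of them acinar-like, against 16 inside it. The leukocyte share of 49.0% cannot tell an isolation that favoured leukocytes from the content of the tissue.

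Acinar enzyme RNA was read in every class, with Ctrb1 at 1228 CPM in T cells and 322 in fibroblasts. Doublets with acinar cells were not borne out, since the 5% of non-acinar cells with most Ctrb1 held 31.8% of its UMIs and 84.9% of non-acinar cells had one. Free RNA could not be told by the written test: the share of Prss2 in Prss2 and Ctrb1 lay up to 10.9 percentage points from the median of 37.5%, in cDC1 at 26.6% (24.2 to 29.0).

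A shallow cluster of 467 cells stayed unnamed although it raised fibroblast markers. The written prediction for fibroblasts of low RNA content or capture was met. This outcome was partly given in advance, since the cluster was picked for its fibroblast markers. The named classes also included no pericyte, mesothelial or Schwann class that its cells could have matched. Of the cluster's cells 99.8% correlated best with the fibroblast profile, as 400 of 400 fibroblasts thinned to its depths did. The same held for 1 of 400 monocyte/macrophages and 0 of 400 T cells. A best match among named classes cannot tell such cells from droplets that hold fibroblast RNA without a cell. Ratios over all other kept cells counted this cluster's 467 cells among the others, and the fibroblast contrasts left them out. Droplets of mostly free RNA failed the written test, but that test cannot decide. The acinar and erythroid markers, which include the haemoglobins, made 3.39% of the cluster's UMIs, below the 49.9% of the excluded barcodes and above the 0.180% of fibroblasts. Over all 521 unnamed cells, Hbb-bs stood at 8304 CPM against 187 in fibroblasts, while Ctrb1 stood at 468 against 322. An Hbb-bs UMI was seen in 59.3% of the unnamed cells and 84.8% of fibroblasts, at median depths of 1791 and 10298 UMIs, so the pooled share need not hold for each cell. Haemoglobin genes alone made 47.5% of the UMIs of the excluded barcodes. Droplets with fibroblast markers could hardly reach that level with or without free RNA.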

How the results depend on the processing

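No paired analysis was possible because each genotype had 1 library. Each value was counted once for every setting it was recomputed under. Of the main values, 218 stayed within their interval or within 1.5 times their count under the settings chosen in advance and 33 moved. Under the 9 settings added after seeing the data 61 stayed and 13 moved. Of other values 379 and 70 stayed, 176 and 5 moved and 1 turned its sign. Part of the 61 was fixed in advance, since leaving out fibroblasts with mesothelial markers could not change the contrasts without fibroblasts. Pairs of list and class above the 97.5th percentile numbered 34 to 42 over the settings. The cause of a change was not tested unless given.

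The leukocyte share was 54.0% with at least 500 genes and, added, 44.9% without a mitochondrial limit. The fibroblast share was 20.2% with at least 500 genes, 22.4% at up to 10% mitochondrial UMIs, 20.5% at resolution 2, 20.8% and 21.7% with 15 and 50 components, 21.3% with list genes in the clustering and 21.6% with another seed. Added settings gave 20.3% with the default neighbour search, 21.5% without the top 4% of doublet scores and 30.5% with the shallow cluster named, by construction. The ductal share was 1.60% with at least 500 genes and 0% with 4000 variable genes, where no cluster took the name. At 500 genes Kras, Trp53 and Setd2 stood at 58.4, 51.9 and 51.4 CPM. Set against the 4056 Setd2 WT barcodes that pass the filter, the Setd2 KO library had 1672 more, by construction. Unfolded protein response genes in B cells reversed to -0.33 without the Jchain cells (added). With classes weighted equally 13 secreted factors had over 50% of UMIs in 1 class.

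Thinning to 1000 UMIs leaves fewer counts and so fewer calls. Higher and lower members were then 34 and 4 for ductal over acinar, 12 and 11 for fibroblast cluster 1, 7 and 17 for cluster 6, 11 and 20 for cluster 13, and 7 and 19 for CD8 over regulatory T cells. Lower members were 13 in monocyte/macrophage cluster 2, and higher ones 12 in cluster 5, 15 in cluster 12 and 14 in T over NK cells. Per-cell CPM gave 12 higher in fibroblast cluster 6, a pseudocount of 5 gave 26 lower in cluster 13, and totals without abundant genes gave 67 higher and 26 lower for ductal over acinar. Without each gene's highest cell (added) 11 were lower for ductal over acinar, and 10 and 19 higher in fibroblast cluster 6 and monocyte/macrophage cluster 12. Without the 5 highest cells (added), recounted, ductal over acinar had 54 higher and 4 lower, fibroblast cluster 6 had 9 and cluster 13 had 12 higher, and monocyte/macrophage cluster 12 had 14 higher and 49 lower. The ductal contrast rests on 18 cells.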

Other observations

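These values were looked for after the results had been seen. The unnamed cluster led by histone genes had 54 cells with a median of 19831 UMIs. With 379 genes that were raised there left out, 29 of its cells correlated best with monocyte/macrophages, 9 with NK cells, 8 with T cells, 7 with cDC2 and 1 with cDC1.

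Tff1, a mucosal trefoil factor, had a UMI in 14 of 86 regulatory T-like cells, 16.3% (9.20 to 25.8), with 71 UMIs of which 22 lay in 1 cell. It was seen in 4 of 211 CD4 T-like cells, 0 of 107 CD8 T-like cells (up to 3.39%) and 0 of 236 NK-like cells (up to 1.55%). Outside the regulatory T-like cells 11 of 3919 kept cells had a UMI, and 1 ductal cell held 1715 of their 1742 UMIs.

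A single barcode held 41373 of the 41491 Ins1 and Ins2 UMIs. Cells with UMIs of over 50% of a marker list numbered 9 for plasma cells, 7 for plasmacytoid dendritic cells, 12 for pericytes or smooth muscle and 5 for mesothelium. There were 0 for lymphatic endothelium, mast cells or basophils, and eosinophils, which does not exclude shallow cells of these types.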
